A study of Mus musculus with 4 samples.

How the data were processed

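Total RNA of 4 CD4+ T cell samples was turned into small RNA libraries with a NEBNext small RNA kit, per the labels' protocols, and sequenced, with 1 library for each combination of genotype (WT or Cbl-b-/-) and state (unstimulated or anti-CD3 for 48 h). Samples were assigned to groups by their source names. Whether a library came from 1 mouse or from pooled mice is not given in the sources used here. The labels call the unstimulated CD4+ T cells naive and give no more on their isolation.

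The authors deposited 2 tables, 1 for the unstimulated and 1 for the stimulated pair of libraries, each with the same 1091 known mature miRNAs. Per the file headers, each table holds a raw read count per miRNA and library. Per the file headers it also holds a normalized read count, a score that equals the count divided by 1 constant per library; from the values, this constant differs from the sum of the counts. The authors' constants imply library totals of 94.4%, 94.7%, 100.1% and 101% of the summed counts for WT and Cbl-b-/- unstimulated and WT and Cbl-b-/- stimulated cells. The deposited tables further give an unadjusted p-value, a linear fold change and a log2 fold change of the 2 libraries, the ratio being WT over Cbl-b-/-, and a call in words. From the values, every call made by the authors had an absolute log2 fold change of at least 1.00, and the highest p-value among them was 0.044. The authors' test is not given in the sources used here, and with 1 library per group its p-values compare 2 libraries. Cutadapt 1.7.1 and the genome build GRCm38.p5 are named per the submitters' processing notes, without their role. The aligner, the counting tool and the miRNA annotation release are not given in the sources used here. From the values, 25 miRNAs in 12 groups, each with at least 20 reads in all, had identical counts in all 4 libraries, so reads that match several miRNAs appear to have been counted for each of them. Such counting raises the sums, and values of miRNAs with near-identical copies are uncertain.

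The deposited counts were the basis of all values reported here. Each count was divided by the sum of counts of its library and multiplied by 1000000 (CPM). Ratios are Cbl-b-/- over WT or stimulated over unstimulated, as log2. Their 95% intervals are exact Clopper-Pearson intervals of the share of a pair's counts in 1 library, turned into a ratio, and cover counting error only. A count of 0 was taken at a floor of 3 counts, which is 0.194, 0.214, 0.229 and 0.259 CPM in the 4 libraries in the order above. edgeR's test, the usual choice for counts, has no residual degrees of freedom in a comparison of 1 library with 1 library, or in a fit that includes the difference between states, so no p-value is given for these. In its place a rule of size was fixed: at least 2-fold, a mean of at least 50 CPM over the libraries compared, and an interval of the log2 ratio that excludes 0. For the difference between states, 0.5 was added to each count, the interval came from a normal approximation, and the rule asked for a difference of at least 1 in log2. The unstimulated and stimulated libraries stand in tables that were normalized separately by the authors; the raw counts, scaled by library sums, were used across them. The spread of log2 ratios is given as a robust SD, the median absolute deviation times 1.4826.

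The 17 miRNA lists were TCR-induced, miR-17~92 and paralogs, resting T cell, let-7, miR-29, miR-30, miR-232724, miR-181, miR-15/16, NF-kB feedback and regulatory T cell associated, Dlk1-Dio3, and 6 lists of other cells (myeloid, erythroid, endothelial and megakaryocyte, stromal, epithelial, liver and muscle). For each list the median log2 ratio of members with a mean of at least 10 CPM was set among 10000 random lists of the same size, matched in 10 bins of level. The percentile describes these libraries and is not a p-value. The groups, comparisons, rule of size, lists and most of the alternatives were fixed before the data were examined. So was the rule for the miRNAs named in the text. It took, for each genotype comparison, up to 10 miRNAs higher and 10 lower past the rule, ranked by ratio. For stimulation it took up to 10 each way past the rule in both genotypes, ranked by the smaller ratio, and for the difference between states up to 5 each way. It added the 5 most abundant miRNAs of each library and the 4 most abundant members of each list. miR-222-3p, miR-221-3p, miR-125b-2-3p, miR-144-3p, miR-342-5p, miR-99b-5p, miR-99b-3p, miR-221-5p, let-7e-5p, and the arm pairs and stromal miRNAs named in the closing section, were chosen after their values were seen.

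Alternatives were TMM factors and DESeq2 size factors, totals without the 10 most abundant miRNAs, level minimums of 10 and 200 CPM and none, fold limits of 1.5 and 4, and counts summed over family members. Added after seeing the data were the library totals implied by the authors' normalized counts, identical rows kept once, the agreement between states without named groups of miRNAs, and an edgeR quasi-likelihood test of genotype and state over all 4 libraries, for miRNAs with a mean of at least 10 CPM. This fit was run with library totals and with TMM factors, and the TMM fit was put first after the calls of both had been seen. The reason was 20 simulated sets with an assumed coefficient of variation of 20% and 40 miRNAs raised 4-fold in Cbl-b-/-. In these, library totals gave a median of 32.5 false calls (at most 232) and found 94% of the planted miRNAs, and TMM factors gave 0.5 (at most 5) and found 99.1%. Neither made a call in 20 sets without a change. All simulated sets left out any difference between states, which most miRNAs showed in the data. They therefore do not show how many false calls the fit makes in these libraries. The raised miRNAs all went 1 way and could be abundant ones, which shifts library totals between the genotypes. In the data, TMM factors moved the pairwise genotype log2 ratios by only -0.05 (unstimulated) and 0.03 (stimulated). The simulated sets therefore do not decide which fit is better for these libraries. Hairpin positions came from GENCODE M21 on GRCm38, the build named by the submitters, matched by name for 1073 of the 1091 miRNAs. The rule of size was tested on simulated counts of 1091 miRNAs with the libraries' own levels and totals, 200 of them changed. In each of the 4 pairwise comparisons it found all miRNAs planted at 3-fold, 4-fold or 0.2-fold above 50 CPM, none planted at 1.5-fold and none left unchanged. These counts held counting error only, which at such levels fixes that outcome, so they check the arithmetic and not the spread between libraries. Further sets assumed a spread of 10%, 20% or 30%. A median of 0, 3 or 22 unchanged miRNAs then passed for unstimulated cells and 0, 3.5 or 26 for stimulated cells. edgeR's additive fit with TMM factors estimated a common coefficient of variation of 0.131 over the 4 libraries, from 1 residual degree of freedom. For the difference between states the rule of size found 100 of 100 planted at 3-fold. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for scaling factors, and edgeR for the additive fit.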

Results

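MicroRNAs, the short RNAs that repress messenger RNAs by base pairing, were measured by small RNA sequencing in CD4+ T cells of C57BL/6 mice. The cells came from wild-type (WT) mice and from mice lacking Cbl-b, an E3 ubiquitin ligase that restrains signalling from the T cell receptor (TCR). Cells of each genotype were left unstimulated or were stimulated with an antibody to CD3, part of the TCR complex, for 48 h. This gave 4 groups with 1 library in each, so no value has a replicate check and a comparison of 2 libraries carries no p-value. The counted reads of known mature miRNAs came to 15436447 in the WT unstimulated library and 14017277 in the Cbl-b-/- unstimulated library. The stimulated libraries held 13074598 (WT) and 11561693 (Cbl-b-/-) reads. Of the 1091 miRNAs listed, 899, 919, 991 and 975 had at least 1 read in these libraries, in that order. Levels are given as counts per 1000000 counted known miRNA reads of a library (CPM). Ratios carry 95% exact Clopper-Pearson intervals, which cover the counting error of reads only and not the spread between libraries. Reads copied by PCR are not independent molecules, so the intervals may be too narrow even for counting error. At 50 CPM the smallest library held 578 reads, for an interval of 46.0 to 54.2 CPM. A miRNA was counted as differing when its ratio was at least 2-fold, its mean level was at least 50 CPM and the interval of the log2 ratio excluded 0. The level of Cblb messenger RNA, the targeted gene on chromosome 16 (GRCm38, 52031225 to 52208048), was not analysed here, so the genotype labels were not checked against it.

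In each library a few miRNAs took most of the reads, the 10 most abundant holding 68.3% in both unstimulated libraries, 64.8% in the WT stimulated and 65.7% in the Cbl-b-/- stimulated library. miR-142a-5p, a miRNA of blood cells in general, was the most abundant without stimulation, at 187887 CPM in WT and 185150 in Cbl-b-/-. miR-181a-5p, known to set TCR sensitivity in developing T cells, followed at 113595 and 109289 CPM. After stimulation miR-21a-5p led, at 219041 CPM in WT and 221297 in Cbl-b-/-, ahead of miR-142a-5p at 121285 and 104582.

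The first comparison asked how the loss of Cbl-b is reflected in the miRNAs of unstimulated CD4+ T cells. Of 197 miRNAs over the level minimum, 3 were higher in the Cbl-b-/- library and 0 were lower. miR-99a-5p stood at 9.91 CPM in WT and 162 CPM in Cbl-b-/-, a 16.3-fold ratio (log2 4.03, interval 3.79 to 4.27). miR-125b-5p stood at 8.03 and 129 CPM, a 16.1-fold ratio (log2 4.01, 3.75 to 4.28). miR-127-3p, from the imprinted Dlk1-Dio3 region, stood at 80.3 and 309 CPM, a 3.84-fold ratio (log2 1.94, 1.85 to 2.04). The hairpin of miR-99a lies on chromosome 16 at 77598936 to 77599000 (GRCm38), in an intron of the noncoding gene Mir99ahg. A copy of the miR-125b hairpin lies in the same gene, at 77646273 to 77646343, and another on chromosome 9, at 41581926 to 41582002. The 3p arm specific to the chromosome 16 copy, miR-125b-2-3p, named here after its values were seen, was higher too, at 2.85 CPM in WT and 76.3 in Cbl-b-/- (log2 4.74, 4.31 to 5.21). The mature sequences of miR-99a and miR-99b, and of miR-125a and miR-125b, are near copies of each other, so reads could be divided between them and these values are uncertain to that extent. With such families summed, 1 miRNA differed in place of 3.

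Among the miRNA lists fixed beforehand, the Dlk1-Dio3 list stood apart. Of its 38 members, 34 were listed and 7 reached a mean of 10 CPM. These 7 were all above a ratio of 1, with a median log2 ratio of 1.96, at the 99.995th percentile of random lists matched on level. The minimum applies to the mean of 2 libraries, so a member high in the Cbl-b-/- library alone could pass it. The members come from 1 region and are not independent, so the percentile overstates how unusual the list is. Besides miR-127-3p its most abundant members were miR-541-5p (log2 1.98), miR-411-5p (1.66) and miR-434-3p (2.25), all below 50 CPM on average. Its hairpins lie on chromosome 12, that of miR-127 at 109592846 to 109592915. Of the 14 TCR-induced miRNAs, 13 were higher in Cbl-b-/-, by little, with a median log2 ratio of 0.25 (99.92th percentile) and 0 past the rule. miR-155-5p, which T cells make from Mir155hg after activation, stood at 2246 CPM in WT and 3112 in Cbl-b-/- (log2 0.47). The list of NF-kB feedback and regulatory T cell miRNAs had a median of 0.21 (98.9th percentile), with miR-146a-5p at 0.40 and miR-125a-5p at 0.62. The resting T cell list had a median of -0.06 (20.1st percentile), although it holds miR-99a-5p and miR-125b-5p, the 2 members past the rule. The medians of the miR-17~92, let-7, miR-29, miR-30, miR-232724, miR-181 and miR-15/16 lists were 0.11, 0.10, 0.02, -0.08, 0.14, -0.11 and -0.08, all inside the central 95% of random lists. The miR-29 median turned to -0.03 with TMM factors and to -0.07 with DESeq2 size factors. Of the 197 miRNAs, 188 (95.4%) lay within 1.5-fold between the genotypes. The spread of their log2 ratios, a robust SD of 0.20, came from 2 libraries alone. Differences between animals, cultures or library preparations were not measured.

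The next comparison asked the same of cells stimulated through CD3. Of 230 miRNAs over the level minimum, 12 were higher in the Cbl-b-/- library and 0 were lower. They included both arms of miR-155, a miRNA needed for full T cell responses. miR-155-5p stood at 25337 CPM in WT and 51621 in Cbl-b-/- (2.04-fold, log2 1.03, interval 1.02 to 1.03), and miR-155-3p at 472 and 1141 CPM (log2 1.27, 1.23 to 1.32). Both arms of miR-31, another activation-induced miRNA, were higher. miR-31-5p stood at 641 and 2032 CPM (3.17-fold, log2 1.67, 1.63 to 1.7), and miR-31-3p at 60.4 and 201 CPM (log2 1.74, 1.62 to 1.85). The hairpin of miR-155 lies in an exon of Mir155hg on chromosome 16 at 84714140 to 84714204, and that of miR-31 on chromosome 4 at 88910557 to 88910662. miR-147-3p (log2 1.06), miR-22-5p (1.27), miR-127-3p (1.48, 1.32 to 1.63) and miR-222-3p (1.03) were also past the rule. miR-6240 had the highest ratio, at 94.7 CPM in WT and 575 in Cbl-b-/- (6.07-fold, log2 2.60, 2.51 to 2.69). Its hairpin is annotated on chromosome 5 at 114851948 to 114852064.

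The other 3 of the 12 were miRNAs of red blood cells. miR-451a stood at 24.4 CPM in WT and 91.8 in Cbl-b-/- (3.76-fold, log2 1.91, 1.73 to 2.10), and miR-486a-5p and miR-486b-5p at 182 and 406, and at 180.4 and 405 CPM (log2 1.16 and 1.17). The miR-486a and miR-486b hairpins lie on opposite strands of 1 locus, so their reads cannot be assigned to either. The 3 measured members of the erythroid list are thus 2 measurements, and its median log2 ratio of 1.17 in the stimulated cells, against 0.22 without stimulation, is that of the miR-486 pair. This difference between the libraries stood beside those of the TCR-induced list, whose median was 0.31, above every random list drawn (100th percentile). Of its 14 members, 13 were higher in Cbl-b-/- and 4 passed the rule: miR-155-5p, miR-155-3p, miR-31-5p and miR-222-3p. miR-210-3p, a miRNA induced in hypoxia, came to log2 0.72 and miR-21a-5p to 0.01. The Dlk1-Dio3 list was again higher, with a median of 1.44 over 4 measured members of the 34 listed (99.8th percentile). miR-99a-5p and miR-125b-5p were below the level minimum, at 1.91 and 3.37 CPM in WT and 50.6 and 57.4 in Cbl-b-/-, with log2 ratios of 4.73 (4.15 to 5.37) and 4.09 (3.65 to 4.57).

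The median of the miR-17~92 list was -0.18 (4.46th percentile), with 10 of 13 members lower in Cbl-b-/- and 0 past the rule; miR-19b-3p stood at -0.59. Medians of the resting T cell, let-7, miR-29, miR-30, miR-232724, miR-181, miR-15/16 and NF-kB feedback lists were -0.16, 0.07, 0.46, -0.15, 0.12, -0.06, -0.12 and 0.17, all inside the central 95% of random lists. Within 1.5-fold lay 204 of the 230 miRNAs (88.7%), and the robust SD of the log2 ratios was 0.26. With DESeq2 size factors 10 of the 12 passed the rule. miR-155-5p and miR-222-3p, both of the TCR-induced list, then came to log2 0.99, below the 2-fold limit. No replicate check exists for these differences either, and they compare 2 libraries, not 2 genotypes.

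**Figure D1:**
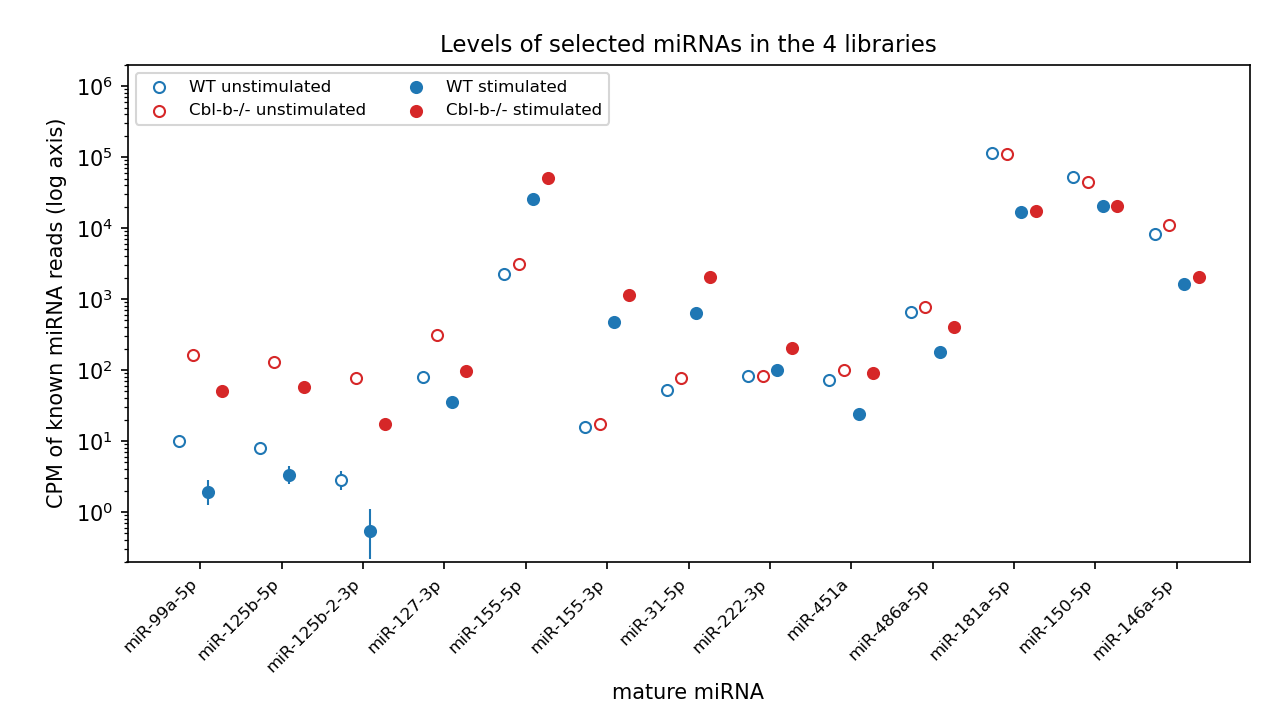
Levels of 13 miRNAs in the 4 libraries, in CPM on a log axis; open points are unstimulated and filled points stimulated cells, blue WT and red Cbl-b-/-, each point 1 library with its 95% Poisson counting interval. miR-99a-5p, miR-125b-5p and miR-125b-2-3p are higher in both Cbl-b-/- libraries, and miR-31-5p reaches 2032 CPM in the stimulated Cbl-b-/- library against 641 in WT.

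The comparison of stimulated with unstimulated cells asked which miRNAs go with activation in each genotype. The libraries compared stand in separate tables, which the authors normalized separately; their counts were scaled here by each library's own total. In WT cells 78 of 220 miRNAs were higher and 31 lower after stimulation, and in Cbl-b-/- cells 78 of 223 were higher and 33 lower. This split depended on the scaling. TMM factors moved every log2 ratio by -0.61 in WT and -0.60 in Cbl-b-/-, giving 49 higher and 69 lower in WT and 52 and 69 in Cbl-b-/-. DESeq2 size factors moved them by -0.52 and -0.45, giving 51 higher and 65 lower, and 57 and 59. Totals without the 10 most abundant miRNAs moved them by -0.20 in both genotypes, giving 65 and 43, and 69 and 46. Of the miRNAs past the rule, 29 in WT and 26 in Cbl-b-/- no longer passed with TMM factors, 27 and 21 with DESeq2 size factors, and 13 and 9 without the 10 most abundant.

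The list of miRNAs known to be induced through the TCR had a median log2 ratio of 3.40 in WT and 3.55 in Cbl-b-/- (100th percentile in both), and 12 and 13 of its 14 members were among the 78 miRNAs past the rule and higher. miR-155-5p was 11.3-fold higher in WT (log2 3.50) and 16.6-fold in Cbl-b-/- (4.05), and miR-155-3p had log2 ratios of 4.91 and 6.03. miR-210-3p was at 17.2 CPM in unstimulated and 889 in stimulated WT cells (log2 5.69), and at 22.8 and 1460 CPM in Cbl-b-/- cells (6.00). Among miRNAs past the rule in both genotypes, the highest ratios also included miR-449c-5p (5.47 and 5.30), miR-147-3p (5.19 and 6.13), miR-298-5p (5.39 and 4.73) and miR-212-5p (4.86 and 4.21). Next came miR-132-5p (3.82 and 3.72), miR-212-3p (3.79 and 3.64), miR-193a-3p (3.64 and 4.59) and miR-31-5p (3.63 and 4.71). miR-132 and miR-212 come from 1 cluster that responds to CREB. In the cluster of miR-182, miR-183 and miR-96, miR-182-5p went from 2158 to 16095 CPM in WT (2.90) and from 2404 to 19634 in Cbl-b-/- (3.03). miR-21a-5p, already abundant, had ratios of 1.74 and 1.47. Of the 13 members of the miR-17~92 list, linked to lymphocyte proliferation, all had ratios above 1 and 8 passed the rule in WT and 6 in Cbl-b-/-. These counts depended on the scaling too. miR-19b-3p was among those that no longer passed in WT and Cbl-b-/- with TMM factors (0.75 in both) and DESeq2 size factors (0.84 and 0.90). The medians of the list, 1.18 and 0.88, were inside the central 95% of random lists. miR-92a-3p, the most abundant, had log2 ratios of 0.81 and 0.82, while members with ratios below the TMM shift, such as miR-93-5p (0.13 and 0.20) and miR-25-3p (0.06 and 0.02), lie below 0 with TMM factors. The miR-232724 list had medians of 1.10 and 0.94, also inside that range.

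Lists of naive and developing T cell miRNAs lay at the lower end, as did lists of other cells, namely the myeloid (0.165th percentile in WT and 1.51st in Cbl-b-/-) and the stromal list (0.115th and 1.48th). The 4 members of the miR-181 list had median log2 ratios of -2.04 in WT (0.155th percentile) and -2.06 in Cbl-b-/- (0.07th), and 3 passed the rule in each. miR-181a-5p went from 113595 to 17100 CPM in WT, 6.64-fold lower, and from 109289 to 17566 in Cbl-b-/-, 6.22-fold lower. The resting T cell list had medians of -0.89 over 8 members in WT (0.98th percentile) and -1.12 over 10 in Cbl-b-/- (0.075th). miR-150-5p, abundant in mature lymphocytes, had log2 ratios of -1.39 and -1.16 and miR-26a-5p of -1.34 and -1.51, while miR-342-5p of the same list was higher, at 2.02 and 1.44. The NF-kB feedback list had medians of -1.37 and -1.12 (1.08th and 1.54th percentiles). In it miR-146a-5p, which restrains NF-kB signalling, stood at -2.34 and -2.44 and miR-10a-5p, associated with regulatory T cells, at -1.91 and -1.90. Among miRNAs past the rule in both genotypes, the lowest ratios included miR-150-3p (-2.96 and -3.26), miR-181a-5p (-2.73 and -2.64), miR-211-5p (-2.54 and -2.47), miR-223-3p of the myeloid list (-2.50 and -2.54) and miR-181b-5p (-2.38 and -2.53). miR-181a-1-3p (-2.36 and -2.37), miR-203-3p of the epithelial list (-2.21 in both) and miR-139-5p (-2.08 and -2.09) followed. Medians of let-7 (-0.14 and -0.20), miR-29 (-0.48 and -0.04), miR-30 (-0.47 and -0.56) and miR-15/16 (-0.65 and -0.42) lay inside the central 95% of random lists.

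Both genotypes responded alike across miRNAs. Of 215 miRNAs over the level minimum in both stimulation comparisons, 68 were past the rule and higher in both, where independent lists would share 26.2, and 27 past it and lower in both, where they would share 4.33. Of the miRNAs past the rule in both, 0 went opposite ways. Across these 215 miRNAs the log2 ratios had a Pearson r of 0.973 and a Spearman rho of 0.980, and 206 had the same sign. The miRNAs are not independent replicates, and each genotype rests on 1 pair of libraries.

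**Figure D2:**
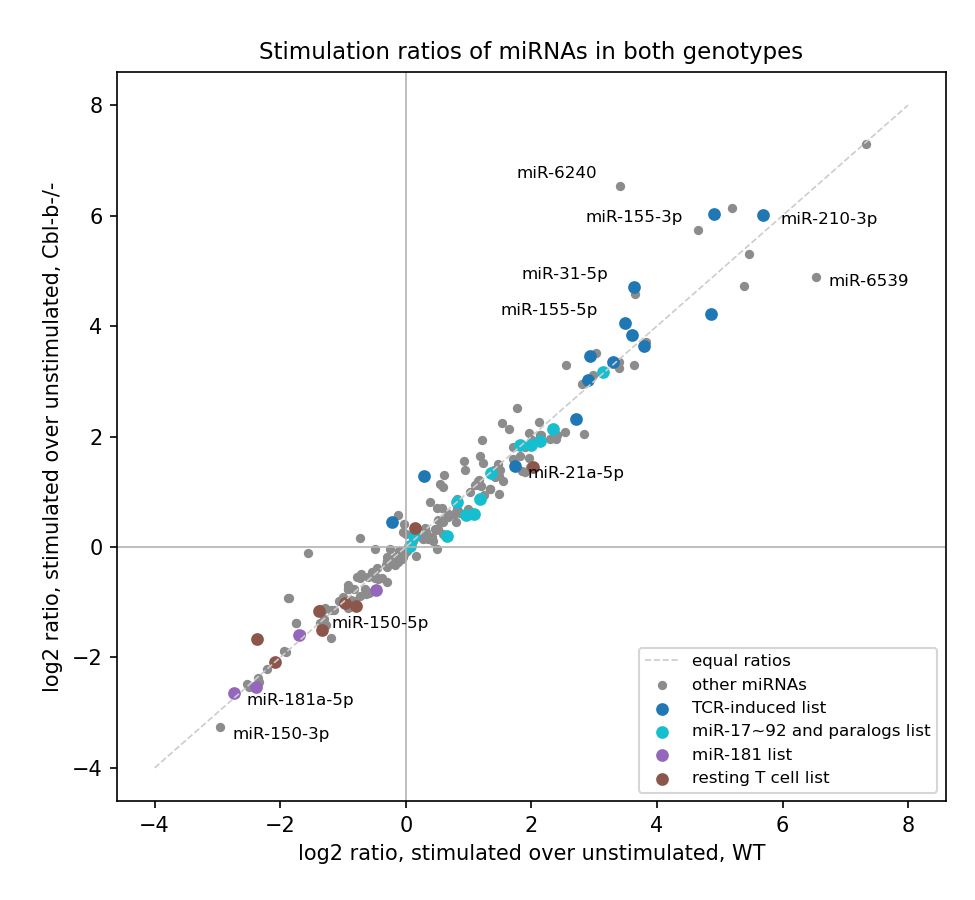
Log2 ratio of stimulated over unstimulated cells in WT (horizontal axis) and in Cbl-b-/- (vertical axis); each point is a miRNA with a mean of at least 50 CPM over the 4 libraries, coloured by list, and the dashed line marks equal ratios. Most points follow the line; miR-6240 lies above it (3.42 in WT and 6.53 in Cbl-b-/-) and miR-6539 below it (6.54 and 4.88).

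The design also asks whether the genotype ratio differs between the states. Of 223 miRNAs with a mean of at least 50 CPM over the 4 libraries, 5 had a ratio of Cbl-b-/- over WT at least 2-fold higher in stimulated than in unstimulated cells and 1 had a lower one. The 5 were miR-6240 (difference of log2 ratios 3.11, 95% counting interval 2.72 to 3.51), miR-451a (1.44, 1.23 to 1.65), miR-155-3p (1.11, 0.86 to 1.37), miR-31-3p (1.08, 0.47 to 1.7) and miR-31-5p (1.08, 0.94 to 1.22). miR-6539, annotated in an intron of Dock5 on chromosome 14 at 67859636 to 67859745, had a difference of -1.64 (-2.41 to -0.88). It rested on 21 and 40 reads in the unstimulated libraries. miR-155-5p had a difference of 0.56 (0.54 to 0.58), and miR-99a-5p, miR-125b-5p and miR-127-3p had differences of 0.68, 0.07 and -0.47. DESeq2 size factors gave 11 miRNAs in place of 6, all higher. With these and with TMM factors miR-6539 kept a difference of -1.53 and -1.63, but its mean level came to 44.1 CPM, under the minimum. Over 184 miRNAs above the level minimum in both states, the genotype ratios of the states had a Pearson r of 0.525 and a Spearman rho of 0.435, with 128 of the same sign. miR-127-3p was the 1 miRNA past the rule in both states. With a minimum of 10 CPM, which lets in more of the Dlk1-Dio3 list, miR-99a-5p and miR-125b-5p, r was 0.781 over 286 miRNAs. The states share no library.

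An additive fit of genotype and state over the 4 libraries, added after seeing the data, leaves 1 residual degree of freedom. It takes the genotype ratio to be equal in both states, so any difference between the states goes into its residual spread. Where both libraries of a genotype came from the same animals, differences between animals would count as genotype. With TMM factors, edgeR's quasi-likelihood test called 3 of 334 miRNAs for genotype at an adjusted p under 0.05, all higher in Cbl-b-/-, with 42 at an unadjusted p under 0.05. The 3 were miR-125b-5p and miR-125b-2-3p (edgeR adjusted p 0.0125 for both) and miR-99a-5p (0.0367), named by their calls. With library totals edgeR called these 3 (adjusted p 0.00215, 0.00215 and 0.0042) and 5 others, namely miR-434-3p, miR-127-3p, miR-411-5p and miR-541-5p, all higher, and miR-19b-3p, lower. miR-155-5p had an edgeR adjusted p of 0.314 with TMM factors and 0.179 with library totals, and miR-31-5p of 0.359 and 0.221. For state, edgeR called 267 miRNAs with TMM factors, 146 higher and 121 lower after stimulation, and 270 with library totals, 174 and 96.

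**Figure D3:**
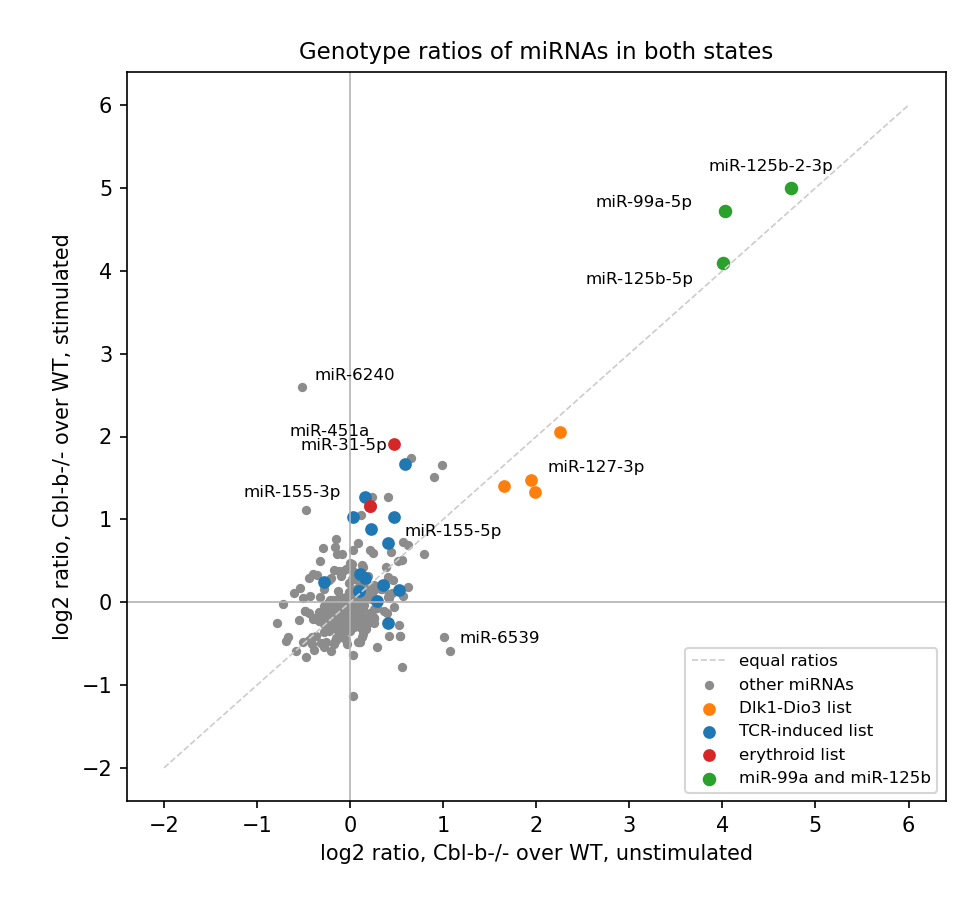
Log2 ratio of Cbl-b-/- over WT in unstimulated (horizontal axis) and stimulated cells (vertical axis); each of the 334 points is a miRNA with a mean of at least 10 CPM over the 4 libraries, and colours mark lists and the miR-99a and miR-125b miRNAs. miR-99a-5p (4.03 and 4.73) and miR-125b-5p (4.01 and 4.09) lie far from 0 on both axes, and miR-6240 (-0.52 and 2.60) on the vertical axis alone.

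Markers of other cells that a CD4+ T cell preparation could hold were followed in 6 lists. The myeloid miR-223-3p was at 464 and 396 CPM in the unstimulated WT and Cbl-b-/- libraries and at 82.3 and 68.2 in the stimulated ones. The myeloid list had median genotype ratios of -0.25 and -0.27 and median stimulation ratios of -3.38 over 2 members in WT and -2.54 in Cbl-b-/-, where miR-223-3p alone was measured; miR-223-3p had -2.50 in WT. The erythroid list was lower after stimulation, with medians, again those of the miR-486 pair, of -1.87 in WT and -0.92 in Cbl-b-/-. The endothelial and megakaryocyte miR-126a-5p was lower in the unstimulated Cbl-b-/- library, at 60.9 against 100.2 CPM, and its list of 2 had a genotype median of -0.75 (0.02nd percentile). The 2 members are the arms of 1 hairpin, miR-126a, and not separate measurements. Set among random pairs of miRNAs, the percentile may therefore overstate how unusual the list is. The genotype median of this list was -0.13 in stimulated cells, and the stimulation medians were 1.38 and 2.0. Of 11 stromal miRNAs, 2 reached 10 CPM, with genotype medians of -0.31 and -0.16 and stimulation medians of -1.65 and -1.50. Epithelial miRNAs had genotype medians of -0.17 and -0.12 and stimulation medians of -0.62 and -0.58. Of the liver and muscle list, 3 of 6 members were listed and 0 reached 10 CPM. The Dlk1-Dio3 list had stimulation medians of -1.14 over 3 members in WT and -1.40 over 8 in Cbl-b-/-.

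The authors' deposited tables give a call for each miRNA between the genotypes. In unstimulated cells the authors' deposited table called 52 miRNAs, 44 of them higher in Cbl-b-/- and 8 higher in WT. For stimulated cells the authors' deposited table called 78, of which 61 were higher in Cbl-b-/- and 17 in WT. Of the calls in the authors' deposited tables, 41 of 52 and 55 of 78 concerned miRNAs with a mean below 10 CPM. The authors' deposited tables included all 3 and all 12 of the miRNAs past the rule of size in those comparisons.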

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

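The tests of explanations in this part were chosen after the results were seen, except that 3 of the 4 other scalings were chosen beforehand. The genotype ratio differed between the states, by more than 2-fold and beyond counting error, for 6 of 223 miRNAs with a mean of at least 50 CPM. These were miR-6240 (3.11 in log2, higher when stimulated), miR-451a (1.44), miR-155-3p (1.11), miR-31-3p (1.08), miR-31-5p (1.08) and miR-6539 (-1.64). With 1 library per group, the spread between animals or preparations was not tested for any of them. With TMM and DESeq2 size factors miR-6539 kept its difference (-1.63 and -1.53) and fell under the level minimum (44.1 CPM), and without the 10 most abundant miRNAs miR-31-5p came to 0.997, under the limit of 1. The genotype comparisons within a state were simulated with an assumed spread between libraries of 10%, 20% or 30% (coefficient of variation). A median of 0, 3 or 22 unchanged miRNAs passed the rule for unstimulated cells and 0, 3.5 or 26 for stimulated cells, over 100 draws each. No such simulation was made for the difference between states, which takes in the spread of 4 libraries, so these counts do not apply to the 6.

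miR-99a-5p, miR-125b-5p and miR-125b-2-3p, and separately the Dlk1-Dio3 miRNAs, were higher in both Cbl-b-/- libraries. Reads wrongly taken from paralogs could leave miR-99b-5p or miR-125a-5p lower in Cbl-b-/-, and their lowest log2 ratio over both states was 0.57. This does not decide it, since a rise of the paralogs could hide such a loss. Reads that match several miRNAs also appear to have been counted for each. The arm specific to the chromosome 16 copy, miR-125b-2-3p, stood at 2.85 CPM in WT and 76.3 in Cbl-b-/- unstimulated cells. Stromal cells, which are rich in several of these miRNAs, would bring miR-145a-5p, miR-199a-3p, miR-199a-5p and miR-214-3p as well, whose summed level was 0.62 CPM higher in unstimulated Cbl-b-/- cells (upper counting bound 3.45), against 152 for miR-99a-5p and 229 for miR-127-3p. Because Cblb and the miR-99a locus lie 25.4 megabases apart on chromosome 16, DNA from another strain beside the targeted gene could differ there and cannot be told apart from the genotype; the 9 chromosome 16 miRNAs before Cblb had a median log2 ratio of 0.057 in unstimulated cells and the miR-155 arms, the miRNAs measured after it besides these, had 0.47 and 0.16, while 0 of the 7 measured Dlk1-Dio3 members lie on that chromosome. An effect of Cbl-b itself, another mix of T cell subsets in cells the labels call naive, and differences between animals stay open.

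miR-451a, miR-144-3p and miR-486a-5p were higher in the stimulated Cbl-b-/- than in the stimulated WT library. Red blood cells carried over in differing amounts may account for this, but cannot be told apart from expression in the T cells. The ratio of miR-451a to miR-144-3p was 11.1 in the stimulated Cbl-b-/- library and 11 in WT. This does not decide between them, since the hairpins lie 100 bases apart and both miRNAs could rise together in T cells as well. Nor does the ratio of miR-486a-5p to miR-451a, 4.43 in the stimulated Cbl-b-/- library and 7.44 in WT, since it differed beyond counting error between the unstimulated libraries as well, at 7.74 and 9.24. All 5 listed erythroid miRNAs were detected in each of the 4 libraries, and no sort against red cells is named in the labels.

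miR-155 and miR-31 were higher in the stimulated Cbl-b-/- library. A response to stimulation larger in proportion for all miRNAs would raise the difference of log2 stimulation ratios. Over the 68 miRNAs higher in both genotypes its median was -0.079, with 30 above 0. The value set by miR-31-5p was reached by 7 of the 68. The median gap to it, 0.68, exceeded the SD of the gaps, 0.61. But miR-31-5p is itself among the 68 and was taken up for its large difference. That most others fall short of it could be foreseen. For the value set by miR-155-5p, reached by 15 of the 68, the gap of 0.40 was below its SD, 0.57. These SDs are the spread between miRNAs and not the error of the median. The comparisons therefore do not decide whether such a response took place, for miR-31 or for miR-155. The values show only that, with library totals, the 68 miRNAs had no larger response in Cbl-b-/- at their median. For miR-155, whose hairpin lies 32.5 megabases from Cblb, DNA beside the targeted gene cannot be told apart from the genotype, and the 10 chromosome 16 miRNAs before Cblb, with a median of -0.033 in stimulated cells, do not decide it; 0 miR-31 hairpins lie on that chromosome. The lowest ratio of miR-155-5p and miR-31-5p over 4 other scalings was 0.99, but these moved ratios by only -0.04 to 0.04 and so do not test the choice of scaling. A stronger response of a subset of miRNAs without Cbl-b, which the design names, and differences in cell state or between cultures stay open as hypotheses.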

How the results depend on the processing

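The library totals implied by the authors and the removal of identical rows were added after seeing the data, as were the agreement values without named miRNAs and the additive fit. No paired analysis was possible because the groups share a single replicate number, which pairs no samples; with state as a term, edgeR's additive fit called 3 miRNAs for genotype with TMM factors and 8 with library totals, which include those 3. At 10 CPM the counts past the rule were 11 and 23 for the genotype comparisons (unstimulated and stimulated), 179 and 182 for stimulation (WT and Cbl-b-/-) and 11 for the difference between states. At 200 CPM they were 0, 6, 57, 58 and 2, and with no minimum 55, 79, 396, 401 and 47, in the same order. By construction these limits change which miRNAs are tested, and low levels carry more counting error. At 1.5-fold the genotype counts were 9 and 26 and that for the difference between states 25. At 4-fold the counts were 1 for the stimulated genotypes, 49 and 48 for stimulation and 1 for the difference between states. With families summed, fewer items were tested, and 1 passed for the unstimulated genotypes and 67 and 63 for stimulation. DESeq2 size factors moved each difference between states by 0.11 in log2, besides changing mean levels, and gave 11. The agreement of genotype ratios between states was 0.781 at 10 CPM, against 0.525 at 50 CPM. At 50 CPM it was 0.458 without miR-99a, miR-125b and the Dlk1-Dio3 list. Of these only miR-127-3p lay above that minimum in both states, so 0.458 is the agreement without miR-127-3p. The agreement at 10 CPM was not computed without them. The other 33 of these values stayed within 1.5 times the main count or within its interval. Of the list medians, 235 kept their place inside or outside the central 95% of random lists, 13 came inside it, 4 went outside it, and 3 near 0 changed sign. Of the values of named miRNAs under other scalings, 327 moved beyond their counting interval, which is narrow at these depths, and 141 did not. Depth limits little at 50 CPM; the lack of replicates limits every comparison.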

Other observations

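What this part reports was chosen after the values were seen, and no explanation was tested. The arms of a hairpin did not always go together after stimulation. Of 42 hairpins with both arms at a mean of 50 CPM or more, 8 had a 5p arm that gained on the 3p arm by over 2-fold in both genotypes, and 5 had a 3p arm that gained on the 5p arm. miR-25-3p stood at 8077 and 8419 CPM in unstimulated and stimulated WT cells (log2 0.06), and at 8868 and 9000.3 in Cbl-b-/- (0.02), while miR-25-5p had stimulation log2 ratios of 2.12 in WT and 2.26 in Cbl-b-/-. For miR-27b the 5p arm gained on the 3p arm by 2.24 and 1.80 in log2, and for miR-150 by 1.57 and 2.10. miR-155 went the other way, by -1.42 and -1.98, as did miR-15b, by -1.96 and -1.51. The miR-669a arms moved apart most, by 3.09 and 2.42, but this family has many near-identical copies and its counts are uncertain. These differences do not depend on the scaling of the libraries, which cancels between arms. Between the genotypes 0 of the 42 hairpins differed by over 2-fold in either state.

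The cluster of miR-99b, let-7e and miR-125a, whose hairpin of let-7e lies on chromosome 17 at 17830352 to 17830444, was higher in Cbl-b-/- in both states by a similar amount. miR-99b-5p had log2 ratios of 0.57 and 0.73 (unstimulated and stimulated), let-7e-5p of 0.51 and 0.49, and miR-125a-5p of 0.62 and 0.69. None of these 3 reached 2-fold, but miR-99b-3p did in stimulated cells, at 2.91 CPM in WT and 6.31 in Cbl-b-/- (log2 1.12, 0.53 to 1.72). miR-221-3p, from the same cluster as miR-222-3p, had a ratio of 0.22 without and 0.88 with stimulation, and its other arm, miR-221-5p, of -0.47 (-0.89 to -0.05) and 1.11. Both arms of miR-22 were higher in the stimulated Cbl-b-/- library, miR-22-3p at 29706 CPM in WT and 48576 in Cbl-b-/- (log2 0.71).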
